A study of Mus musculus with 12 samples.

How the data were processed

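Total RNA in 12 samples of whole testis from mice aged 10 days was measured on Illumina MouseWG-6 v2 BeadChips, arrays that carry oligonucleotide probes on beads. Per the labels' protocols, mice carrying Cre recombinase under the anti-Müllerian hormone promoter, which is active in Sertoli cells, were crossed with mice carrying floxed copies of Rb1, the gene of the retinoblastoma protein. RNA was taken with Trizol, cleaned on RNeasy columns with DNase I, amplified and biotinylated, per the labels' protocols. The labels place 5 arrays in the wild type group (WT, replicates 8 to 12), 3 in the group with Rb1 deleted on 1 allele in Sertoli cells (HET, replicates 5 to 7) and 4 in the group with the deletion on both alleles (KO, replicates 1 to 4). No replicate number occurs in more than 1 group, so no samples were paired. No label says that each RNA came from a different mouse or litter, so p-values measure the spread between these samples.

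The deposited table of unnormalized values gives a mean bead intensity on a linear scale and a detection p-value for each of 45281 probes on each array, per the file headers. The scanner software is not given in the sources used here. The authors' processed values, deposited as intensity on a linear scale, had the same distribution on all 12 arrays to within 1 percent at every rank, with a median of 56.2. Each array's values had a rank correlation of 1 with that array's own unnormalized intensities. They differed from a quantile normalization of the unnormalized intensities by at most 4.87e-08 percent. Scale and normalization of these values are therefore known, and they are not centred. They were used as an alternative only.

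Analysis was done in R 4.3.3 with limma 3.58.1, with data.table at 1.17.8, and plots were made with Python 3.11.15 and matplotlib 3.10.9. Unnormalized intensities were background-corrected by normexp, with the background taken from the detection p-values and an offset of 16, quantile normalized and taken to log2 (limma's neqc). Probes detected at p under 0.05 on at least 3 arrays were kept, which left 20170 probes. Gene names came from the platform annotation. Of all probes, 34885 had 1 gene symbol, 18 had several and 10378 had none in the table used here. Symbols were looked up by Entrez identifier in the GRCm38.p6 gene table, where 34807 probes matched and 0 symbols changed. Each gene was represented by its detected probe with the highest mean, giving 11076 genes, of which 4174 had more than 1 detected probe. Of the named gene entries, 5 of 94 in KO against WT, 10 of 94 in HET against WT and 8 of 94 in KO against HET had another detected probe with a difference of the opposite sign. Probe sequences were not used here, and because the deposited files name no genome build, no coordinates are given.

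Groups were compared with 1 limma fit (lmFit, eBayes) over all 12 arrays, with 3 contrasts and an F-test over both contrasts against WT, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. A total of 22 gene lists for testicular cell types, the cell cycle and possible tissue admixture was fixed before the data were examined, as were the tests and all alternatives except those said to be added. Lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. The estimated correlation was run over all 12 arrays, and in the block fit described below. Its adjusted p-values therefore do not retest calls made in other settings. An exact two-sided permutation test of the list mean per array was added after seeing the data. The named genes, by a rule also fixed then, were Rb1, the genes past the threshold with the largest differences or, since fewer than 5 passed, the 5 with the smallest p-values (leaving out Riken, Gm, LOC and EST style names), and the 4 members of each list with the smallest p-values. The procedure was tested on simulated data made from the residuals of the 11076 genes for KO against WT. With arrays shuffled together, 42.1 percent of genes changed by 0.5 on the log2 scale were recovered, 91.1 percent of those changed by 1 and 98.8 percent of those changed by 2, with a mean of 6.45 false calls per draw among the genes left unchanged, 200 genes being changed in each draw.

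Alternatives were normalization without background correction, an offset of 50, scaling to the same median, the authors' values, no filter or a stricter filter on dim probes (detection p under 0.01 on every array of a group), the mean of a gene's probes, fits on only the groups compared, an intensity trend with a robust prior, array weights, WT and HET together as the control, and each array left out in turn. Leaving out WT 12, HET 6 and HET 7 together, testing each detected probe singly, the mean of the meiotic list as a covariate, and the lists without their members Fcer1g and F11r were added after seeing the data. So was a block for the lower and upper 6 of the numbers in the column names of the unnormalized table, a split that was noticed because the Y-linked Eif2s3y probe parts the arrays in the same way. The slide of each array is not given in the sources used here, so the planned slide block was not run. Array correlations over the 11076 genes lay between 0.9605 and 0.9946, and no array was a copy of another. The number of arrays limits the precision.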

Results

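Gene expression was profiled in whole testes of 10-day-old mice with Sertoli cell-specific deletion of Rb1. The comparison addressed the role of the retinoblastoma protein, which restrains entry into the cell cycle by binding E2F transcription factors, in Sertoli cells, the somatic cells that support germ cells. There were 5 WT arrays, 3 HET arrays (SC-Rb+/-) and 4 KO arrays (SC-RbKO). Between 39.3 and 43.7 percent of the 45281 probes were detected per array, and the median unnormalized intensity lay between 52.2 and 60.2. All levels below are log2 normalized intensities, given as mean ± SD.

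Rb1 lies on chromosome 14 and was measured by 2 probes. The brighter probe read 9.07 ± 0.19 in WT (n = 5), 9.04 ± 0.22 in HET (n = 3) and 8.82 ± 0.30 in KO (n = 4). Its difference between KO and WT was -0.26 (SE 0.15, limma unadjusted p = 0.1, adjusted p = 1), and -0.41 without KO 1 and -0.19 without KO 4. Its difference between HET and WT was -0.03, and -0.22 with the mean of both probes, but 0.09 without HET 5. It was -0.31 without WT 12, HET 6 and HET 7, a choice made after seeing the data that leaves HET 5 as the only HET array. The dimmer probe read 7.80 ± 0.22 in WT, 7.38 ± 0.06 in HET and 7.33 ± 0.29 in KO. Its differences from WT were -0.47 (SE 0.14) in KO and -0.41 (SE 0.15) in HET. For these, limma gave unadjusted p-values of 0.0058 and 0.019, and adjusted p-values of 1 and 0.47 over all detected probes. The KO difference was -0.26 with WT and HET together as the control. Array KO 1 read 9.26 and 7.74 on the brighter and the dimmer probe, within the range of the WT arrays. The position of these probes relative to the deleted part of the gene was not analysed here, and Rb1 was deleted in Sertoli cells while RNA was of the whole testis, so these values do not check the genotype labels.

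**Figure D1:**
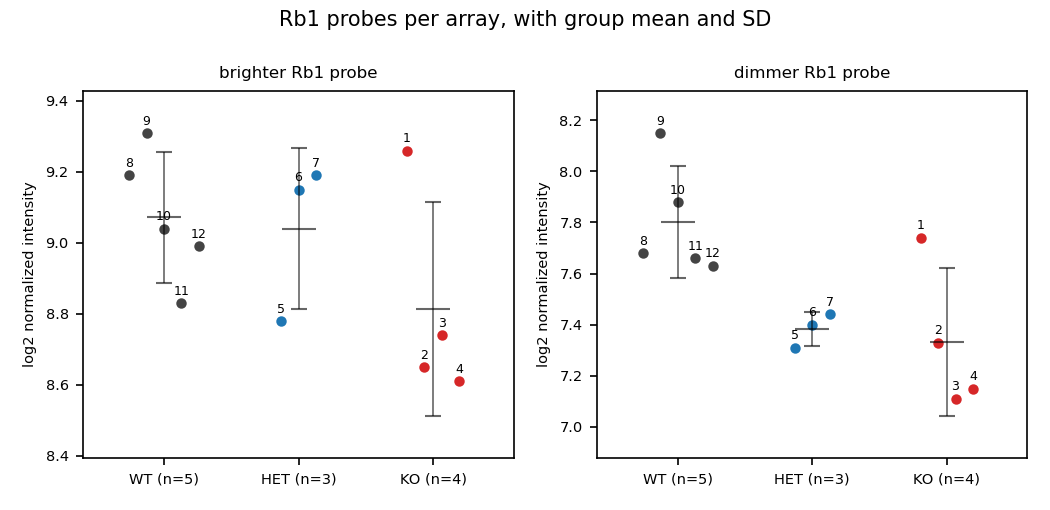
Log2 normalized intensity of both Rb1 probes on each array (points, numbered by replicate) for the 5 WT, 3 HET and 4 KO arrays, with the mean and SD of each group. KO 1 reads 9.26 on the brighter probe and the other KO arrays read 8.61 to 8.74.

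Arrays differed in meiotic transcripts within groups. Ldhc and Piwil1 were chosen after their values were seen. Ldhc, a lactate dehydrogenase of spermatocytes and sperm, read 10.55 in WT 12 and 11.51 in HET 7, 5.25 in HET 6, and 6.34 to 8.09 in the other arrays. Piwil1, a piRNA-binding protein of spermatocytes, read 9.98, 10.56 and 6.52 in WT 12, HET 7 and HET 6. The mean of the 22 measured members of the meiotic prophase list, relative to the WT mean, was 0.68 in WT 12, 0.75 in HET 7 and -0.89 in HET 6, and between -0.30 and 0.11 in the remaining arrays. The spermatogonia list differed by -0.08, -0.13 and 0.02 in those 3 arrays. The SD of an array's genes about the median array was 0.44 in HET 6, 0.37 in HET 7 and 0.30 in WT 12, and 0.17 to 0.24 in the others.

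**Figure D2:**
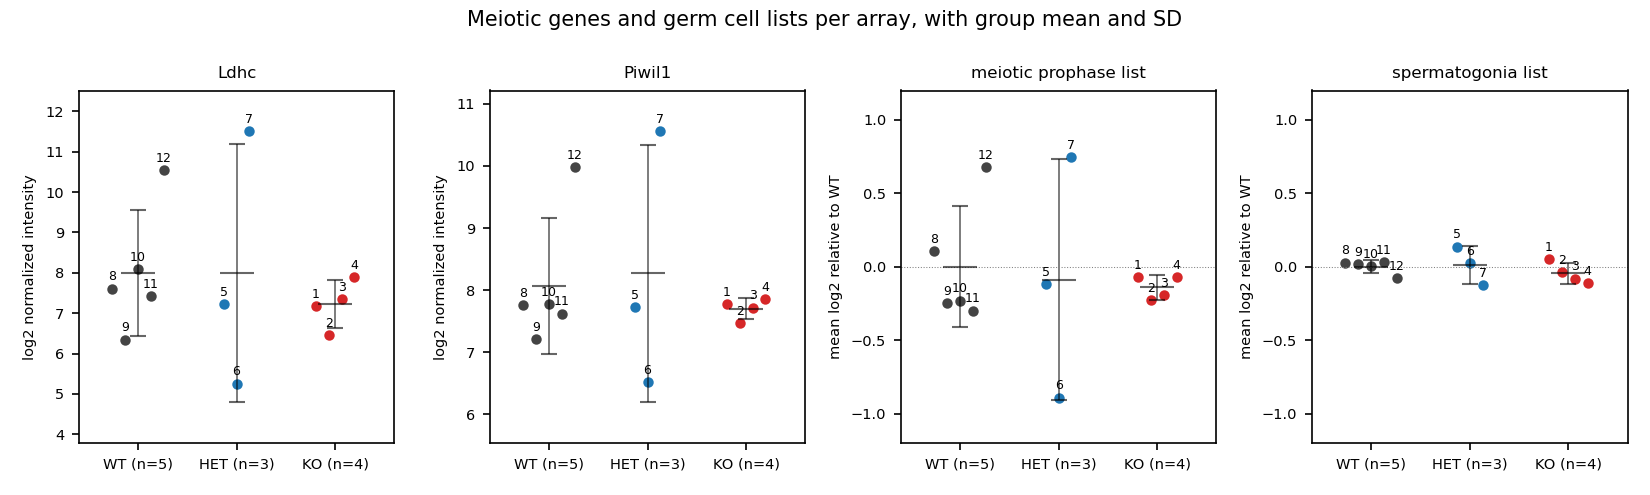
Log2 normalized intensity of Ldhc and Piwil1, and mean log2 of the meiotic prophase and spermatogonia lists relative to the WT mean, on each array (points, numbered by replicate), with the mean and SD of each group. WT 12 and HET 7 lie above and HET 6 below the other arrays for the meiotic genes, and the spermatogonia list spans -0.13 to 0.14.

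The first comparison asked how loss of both Rb1 copies in Sertoli cells alters testicular expression. Genes with the smallest p-values were all higher in KO than in WT. Plcd3, a phospholipase C, was higher by 0.36 (SE 0.08), Diaph3, a formin that nucleates actin filaments, by 0.41 (SE 0.10), and Chek1, a DNA damage checkpoint kinase, by 0.52 (SE 0.12). Jade2 differed by 0.38 (SE 0.10), and like Chek1 was detected on 3 of 5 WT arrays. Crocc, a component of the ciliary rootlet, differed by 0.30 (SE 0.08). All 4 KO arrays lay above every WT array for Plcd3, Diaph3, Jade2 and Crocc, and 3 of 4 did for Chek1. None of these passed correction for 11076 genes (limma adjusted p = 1 for each). They were chosen by p-value on these same arrays, so their separation is no further support. Over all 11076 genes, KO and WT arrays did not overlap for 215 (1.94 percent), where 176 (1.59 percent) are expected by chance. In limma 0 genes passed the threshold, 284 had an unadjusted p under 0.05 (178 higher and 106 lower in KO) where 554 are expected by chance, and 10 differed by at least 2-fold. Without WT 12, HET 6 and HET 7, a choice made after seeing the data, 2 genes passed: Prcp (-0.82, adjusted p = 0.019) and Sncb (0.82, adjusted p = 0.045), named after their values were seen. In the left-out WT 12, Prcp read 8.61 and Sncb 7.34, against 8.49 to 8.66 and 6.77 to 7.17 in KO.

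Among the gene lists, E2F targets of the G1/S transition and DNA replication were higher in KO than in WT. The mean over the list was 0.10 ± 0.06 relative to WT (SD, n = 4) against 0 ± 0.07 in WT (n = 5), and 38 of 51 measured members were above 0 with a median of 0.085. Chaf1b, a histone chaperone subunit, read 9.12 ± 0.19 in KO and 8.78 ± 0.11 in WT, Pola2, a DNA polymerase subunit, 8.46 ± 0.08 and 8.13 ± 0.14, and the replicative helicase subunit Mcm2 10.51 ± 0.05 and 10.21 ± 0.14. Mcm4 read 11.79 ± 0.08 and 11.56 ± 0.07. In all, 0 members passed the threshold over all genes and 0 when adjusted over the list alone. The list passed with the preset correlation (camera adjusted p = 1.6e-06), but had adjusted p = 0.22 with an estimated correlation and an exact two-sided permutation p of 0.079, and 2 of 4 KO arrays lay above every WT array. The related lists, the first of which shares 6 genes with the E2F targets, did not pass over all arrays. Of the Rb and E2F network, 15 of 27 members were above 0 (median 0.044, camera adjusted p = 0.17), with E2f1, itself an E2F target, at 9.78 ± 0.19 in KO and 9.51 ± 0.13 in WT. Of the G2/M and mitosis list, 22 of 32 members were above 0 (median 0.052, camera adjusted p = 0.17), with Foxm1 at 7.67 ± 0.06 and 7.43 ± 0.13 and Tpx2, detected on 3 of 4 KO arrays, at 5.33 ± 0.24 and 5.62 ± 0.19. The G2/M list passed without WT 8 (median 0.083, camera adjusted p = 0.0088), with array weights (0.072, 0.011) and with the stricter filter (0.056, 0.038). Over all arrays it had adjusted p = 0.79 with an estimated correlation. The Rb and E2F network passed without KO 1 (0.075, 0.018), and over all arrays had adjusted p = 0.36 with an estimated correlation.

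Markers of Sertoli cells did not pass as groups over all arrays. The Sertoli cell identity list had a median of -0.028 over 26 members (camera adjusted p = 0.16), the immature Sertoli cell list -0.001 over 9 (0.92), the Sertoli cell maturation list -0.025 over 21 (0.86), the blood-testis barrier and junctions list 0.016 over 20 (0.87, and 0.004 and 0.92 without F11r, a member that switched between levels across arrays) and the Sertoli niche and hormone signals list 0.019 over 17 (0.93). The identity list passed, lower in KO, without WT 8 (median -0.06, camera adjusted p = 0.036), without WT 12 (-0.079, 0.014), with array weights (-0.083, 0.017) and, in settings added after seeing the data, with the meiotic covariate (-0.075, 0.014) and without WT 12, HET 6 and HET 7 (-0.079, 0.0093). Without WT 9 its median was 0.0068 (0.55), and over all arrays its adjusted p was 0.71 with an estimated correlation. The thyroid hormone receptor gene Thra read 6.49 ± 0.05 in KO and 6.22 ± 0.19 in WT, and the tight junction gene Ocln 7.87 ± 0.12 and 7.63 ± 0.11. Hsd17b1 read 8.65 ± 0.33 in KO and 9.08 ± 0.59 in WT, and the dopamine receptor gene Drd4 10.59 ± 0.26 and 10.99 ± 0.35.

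The pan-germ cell list was lower in KO than in WT, with 18 of 23 members below 0 and a median of -0.058 (camera adjusted p = 0.0049). It had adjusted p = 0.36 with an estimated correlation, and camera adjusted p = 0.058 without WT 12, in which meiotic genes were high. Stk31, detected on 2 of 4 KO arrays, read 5.15 ± 0.18 in KO and 5.57 ± 0.20 in WT, the pluripotency-associated gene Dppa4 9.30 ± 0.17 and 9.56 ± 0.05, and Piwil2, a piRNA pathway gene that lies within 10 Mb of Rb1 in GRCm38.p6 and was low in the same KO and WT arrays as its neighbour Esd, 9.60 ± 0.04 and 10.21 ± 0.78. The spermatogonia list had a median of -0.049 over 29 members (camera adjusted p = 0.17), with Neurog3, a marker of differentiating progenitors, at 7.61 ± 0.08 and 7.86 ± 0.19. The spermatogonia list passed without KO 1 (median -0.092, camera adjusted p = 0.031), without WT 12 (-0.058, 0.049) and, chosen after seeing the data, without WT 12, HET 6 and HET 7 (-0.058, 0.046). Over all arrays it had adjusted p = 0.71 with an estimated correlation. The meiotic prophase list had a median of -0.104 over 22 members (camera adjusted p = 0.18). It passed without WT 10 (-0.18, 0.027) and without WT 11 (-0.193, 0.012), and over all arrays had adjusted p = 0.94 with an estimated correlation.

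Other cell types of the testis were measured alongside. The Leydig cell and steroidogenesis list was lower in KO, with 10 of 14 members below 0 and a median of -0.138 (camera adjusted p = 0.0074, adjusted p = 0.19 with an estimated correlation). The list mean relative to WT was -0.258 in KO 1 and -0.299 in KO 3, -0.118 in KO 2 and -0.022 in KO 4, and was also low in WT 11 (-0.152), HET 5 (-0.36) and HET 7 (-0.154). Star, which carries cholesterol into mitochondria, read 5.08 ± 0.56 in KO and 5.78 ± 0.74 in WT, and was detected on 1 of 4 KO and 4 of 5 WT arrays. Insl3, a Leydig cell hormone, read 10.49 ± 0.24 and 10.69 ± 0.17. The peritubular myoid and smooth muscle list was higher in KO, with 14 of 16 members above 0 and a median of 0.088 (camera adjusted p = 0.0049, adjusted p = 0.22 with an estimated correlation). Tagln read 7.00 ± 0.18 in KO and 6.69 ± 0.23 in WT, and Actg2, smooth muscle gamma actin, 9.16 ± 0.23 and 8.87 ± 0.21. The macrophage list was lower, with 16 of 21 members below 0 and a median of -0.124 (camera adjusted p = 0.0049, adjusted p = 0.54 with an estimated correlation), Aif1 reading 6.76 ± 0.23 and 7.03 ± 0.09. Its member Fcer1g switched between levels across arrays, reading 8.28 and 8.14 in KO 1 and KO 2, and 4.42 and 4.34, not above background, in KO 3 and KO 4. Without it the list means of KO 1 and KO 2 were -0.179 and -0.255, in place of -0.026 and -0.104, and the list median was -0.135 (camera adjusted p = 0.0033), in an analysis added after seeing the data. The immediate early and heat shock response list, whose genes react to handling of tissue, was lower as well, with 15 of 19 members below 0 and a median of -0.119 (camera adjusted p = 0.026, adjusted p = 0.49 with an estimated correlation).

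Single arrays and settings ended several of these calls or moved their medians, given here with camera adjusted p-values. The pan-germ cell list had a median of -0.019 without WT 12 (0.058), also left out with HET 6 and HET 7 (0.072), and -0.023 with array weights (0.14). Its median was -0.116, -0.12, -0.107 and -0.089 without WT 10, WT 11, KO 1 and KO 2, -0.099 with WT and HET together as the control and -0.03 with the meiotic covariate, and it passed in these. The Leydig list had -0.111 without WT 9 (0.11), -0.099 without KO 3 (0.057), -0.068 with no filter (0.052) and -0.03 with WT and HET together (0.38). The peritubular list had 0.074 without KO 2 (0.058) and 0.099 with WT and HET together (0.072). The macrophage list had -0.098 without WT 11 (0.16), -0.092 without KO 3 (0.086) and -0.028 with WT and HET together (0.23), and passed with -0.202 without WT 8 and -0.204 without KO 4. The immediate early list had -0.033, -0.142, -0.119, -0.071, -0.11 and -0.082 without WT 9 (0.55), WT 10 (0.10), HET 6 (0.051), KO 1 (0.082), KO 3 (0.13) and KO 4 (0.076). It also had -0.082 with no filter (0.11), -0.119 with only the groups compared (0.052) and -0.069 with WT and HET together (0.32), and passed with -0.185 without WT 12, -0.192 without KO 2, -0.076 without background correction or in the authors' values and -0.075 with an offset of 50. In all, 6 of 22 lists passed in KO against WT with the preset correlation, 0 with an estimated one and 0 by the exact permutation test after adjustment, whose smallest possible p is 0.016, so that 7 lists at that p would be needed for any to pass. Unadjusted fry p-values were 0.035 for the E2F targets, 0.026 for the Leydig list and 0.029 for the peritubular list. They were 0.15 for the pan-germ cell list, 0.3 for the macrophage list and 0.25 for the immediate early list.

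The Y-linked probe of Eif2s3y was detected on exactly the 6 arrays with the lowest numbers in the column names of the unnormalized table (WT 8, WT 9, HET 5, HET 6, KO 1 and KO 2), called the low-number set below, the other 6 being the high-number set. What these numbers stand for is not given in the sources used here. With both sets as a block, a choice made after seeing the data, the same 6 lists passed in KO against WT with the preset correlation and 0 with an estimated one, and in limma 0 genes passed (290 at an unadjusted p under 0.05). The E2F target mean differed between KO and WT by 0.044 in the low-number set (2 KO and 2 WT arrays) and 0.131 in the high-number set (2 and 3). Its exact two-sided permutation p over the 60 arrangements within sets was 0.083, and its adjusted p was 0.22 with an estimated correlation in the block fit. The macrophage list mean differed by 0.122 in the low-number set and -0.215 in the high-number set, but by -0.064 and -0.154 without Fcer1g, so that the opposite directions rest on that gene. In the same order the differences were -0.107 and -0.155 for the pan-germ cell list, -0.273 and -0.104 for the Leydig list, 0.128 and 0.069 for the peritubular list and -0.152 and -0.105 for the immediate early list. The pan-germ cell difference in the high-number set rests largely on WT 12 (0.254). WT 10 and WT 11 had means of -0.091 and -0.14, against -0.143 and -0.152 in KO 3 and KO 4.

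**Figure D3:**
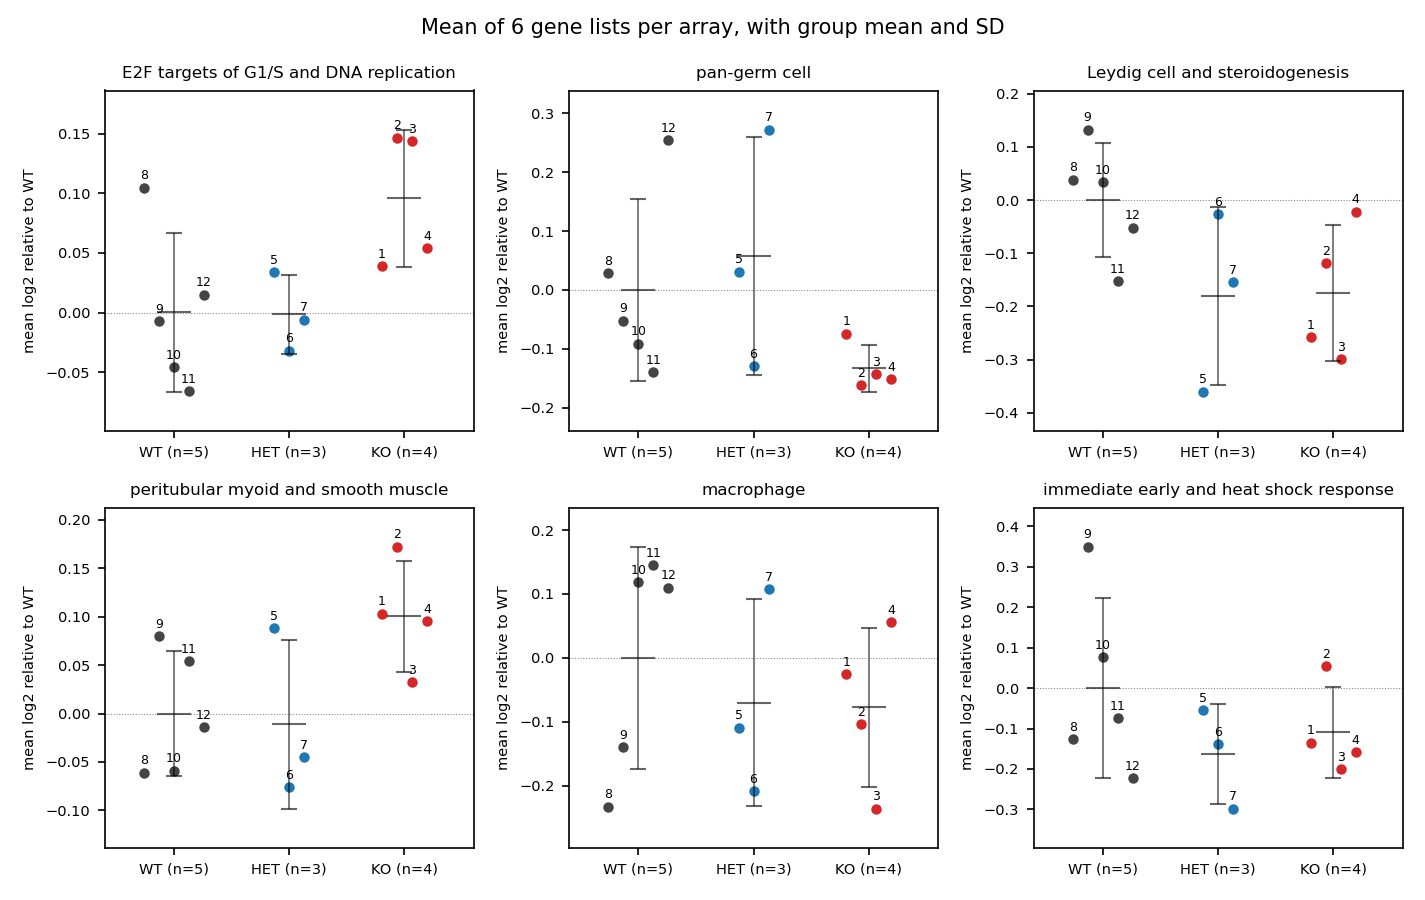
Mean log2 of the 6 gene lists that passed with the preset correlation in KO against WT, relative to the WT mean, on each array (points, numbered by replicate), with the mean and SD of each group. For the E2F targets the 4 KO arrays lie between 0.039 and 0.147, and WT 8 lies at 0.105, while the macrophage means include Fcer1g, which switched between levels.

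The remaining lists did not pass in KO against WT over all arrays. Medians were 0.015 for stromal and extracellular matrix genes (camera adjusted p = 0.45), -0.024 for endothelial genes (0.51), 0.066 for erythroid genes (0.87), 0.007 for genes of epididymis, fat and striated muscle (0.93), 0.002 for p53 targets and apoptosis (0.92), 0.067 for cholesterol synthesis and uptake (0.32) and 0.009 for the interferon response (0.69). The stromal list passed without KO 3 (median 0.079, camera adjusted p = 0.027), and over all arrays had adjusted p = 0.94 with an estimated correlation. Within it, Col1a1, a chain of type I collagen, read 11.48 ± 0.24 in KO and 10.97 ± 0.25 in WT (limma adjusted p = 1). In each of the 22 lists, 0 members passed over all genes and 0 when adjusted over the list alone.

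The second comparison asked whether loss of 1 Rb1 copy alters expression. The 5 genes with the smallest p-values were Zfp760 (-0.47, SE 0.10), Prf1, the cytolytic protein perforin (-1.12, SE 0.23), Dusp26, the ubiquitin ligase gene Cbl (0.55, SE 0.12) and Ice2 (-0.58, SE 0.13), each with limma adjusted p = 0.50. Dusp26 was not above background on any HET array and was detected on 3 of 5 WT arrays. No fold is given for it, since the other 2 WT readings were not above background either. In limma 0 genes passed in HET against WT, and 1082 had an unadjusted p under 0.05 (407 higher and 675 lower in HET). Without HET 5, which leaves HET 6 and HET 7 with their opposite meiotic levels, 173 genes passed (37 higher in HET), Prf1 and Ice2 among them. With the preset correlation 0 of 22 lists passed. The E2F target list had a median of 0 with 25 of 51 members above 0 (camera adjusted p = 0.72), and the G2/M and mitosis list a median of 0.084 with 22 of 32 above 0 (0.071). The G2/M list passed without WT 8 (0.108, 0.0037), without HET 5 (0.15, 0.032), without HET 6 (0.094, 0.02), with array weights (0.088, 0.0043) and with the stricter filter (0.087, 0.041). Over all arrays it had adjusted p = 0.83 with an estimated correlation. Of the Leydig list 13 of 14 members were below 0 (median -0.067, camera adjusted p = 0.18), with Insl3 at 10.21 ± 0.27 in HET and 10.69 ± 0.17 in WT. The Leydig list passed without HET 6 (-0.167, 0.0055) and with array weights (-0.221, 0.01), and over all arrays had adjusted p = 0.80 with an estimated correlation. Its median was -0.242 without WT 12, HET 6 and HET 7, a choice made after seeing the data that leaves HET 5 as the only HET array. Adjusted over the list alone, 1 of 29 spermatogonia genes passed, Cdh1 (-0.42, adjusted p = 0.021), which was detected on 1 of 3 HET and 5 of 5 WT arrays, so that the HET level is near background. Without HET 6, 5 lists passed, among them the meiotic prophase list, whose median was 0.26 (camera adjusted p = 0.0049). Without HET 7 that list passed in the opposite direction, with a median of -0.40 (0.00039). It also passed with array weights (0.172, 0.016), and over all arrays its median was -0.122 (0.56), with adjusted p = 0.87 with an estimated correlation. Without WT 12, HET 6 and HET 7, chosen after seeing the data, HET 5 is the only HET array, so only medians are given for 3 further lists. These were 0.103 for the spermatogonia list (-0.013 over all arrays), -0.08 for the cholesterol list (-0.022) and 0.142 for the epididymis, fat and striated muscle list (-0.092). Over all arrays their adjusted p-values with an estimated correlation were 0.87, 0.83 and 0.87 in turn. The pan-germ cell list, with a median of 0.036 over all arrays (0.35), passed with array weights (0.13, 0.015) and without HET 6 (0.135, 0.028). The immature Sertoli cell list (-0.201, 0.18) passed without HET 6 (-0.189, 0.028), and the endothelial list (-0.141, 0.18) without HET 5 (-0.226, 0.032). Over all arrays the pan-germ cell, immature Sertoli cell and endothelial lists each had adjusted p = 0.83 with an estimated correlation.

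The third comparison set KO against HET. Tbata, a testis and brain gene, was higher in KO by 0.89 (SE 0.18), Ppp1r14a, an inhibitor of myosin phosphatase, by 1.00 (SE 0.22), Diaph3 by 0.53 (SE 0.11) and Nmral1 by 0.50 (SE 0.11), while Ccdc136 differed by -0.71 (SE 0.15), each with limma adjusted p = 0.66. In limma 0 genes passed and 775 had an unadjusted p under 0.05 (507 higher and 268 lower in KO). Without HET 5, 62 genes passed (50 higher in KO). E2F targets were higher in KO with 39 of 51 members above 0 and a median of 0.097 (camera adjusted p = 0.017), and the pan-germ cell list was lower with 17 of 23 below 0 and a median of -0.18 (0.0065). Each had adjusted p = 0.76 with an estimated correlation. Within the germ cell lists, Ddx4, a germ cell RNA helicase, read 7.16 ± 0.21 in KO and 7.91 ± 0.44 in HET, and Piwil2 9.60 ± 0.04 and 10.79 ± 0.41. Piwil2 lies near Rb1 and parted the arrays as its neighbour Esd did, and the pan-germ cell list was not run without it. Adjusted over the list alone, the spermatogonia genes Id4 (-0.61, adjusted p = 0.04) and Neurog3 (-0.44, adjusted p = 0.04) and the muscle troponin gene Tnni2 (0.69, adjusted p = 0.038) passed. Without HET 5 the E2F target and pan-germ cell lists had medians of 0.126 and -0.203 (camera adjusted p = 0.12 and 0.094), and without HET 7 of 0.084 and -0.048 (0.057 and 0.33). The E2F target list also had 0.086 without KO 2 (0.10) and 0.065 without KO 3 (0.098), and a median of 0.057 without WT 12, HET 6 and HET 7, which leaves HET 5 as the only HET array. The pan-germ cell list passed with -0.288 without HET 6, -0.116 with array weights, -0.093 with scaling to the same median and -0.071 with no filter. Without the 3 arrays its median was -0.079. In the low-number set (2 KO and 2 HET arrays) the KO and HET means differed by 0.092 for the E2F targets and by -0.069 for the pan-germ cell list. In the high-number set they differed by 0.105 and -0.419, but there HET 7 is the only HET array, set against 2 KO arrays. The immature Sertoli cell list, with a median of 0.221 over all arrays (camera adjusted p = 0.15), passed without HET 6 (0.227, 0.025), without KO 3 (0.248, 0.03), with no filter (0.22, 0.046), with the mean of a gene's probes (0.221, 0.036) and, chosen after seeing the data, with both number sets as a block (0.236, 0.048). The cholesterol list (0.089, 0.19) passed without HET 6 (0.141, 0.025) and with array weights (0.106, 0.027). Over all arrays the immature Sertoli cell and cholesterol lists each had adjusted p = 0.76 with an estimated correlation. The spermatogonia list (-0.045, 0.19, and 0.77 with an estimated correlation) passed without HET 7 (-0.106, 0.034) and with array weights (-0.044, 0.027). The meiotic prophase list (-0.012, 0.83) passed in opposite directions without HET 6 (-0.356, 1.9e-05) and without HET 7 (0.339, 0.0095), and with array weights was lower in KO (-0.159, 0.012). Over all arrays it had adjusted p = 0.96 with an estimated correlation. Without WT 12, HET 6 and HET 7, chosen after seeing the data, HET 5 is the only HET array, so only medians are given. These were 0.142 for the cholesterol list, -0.131 for the spermatogonia list and -0.119 for the endothelial list. Over all arrays the endothelial list had a median of 0.142 (0.28), and adjusted p = 0.93 with an estimated correlation. An F-test in limma over both contrasts against WT gave 0 genes, with 602 at an unadjusted p under 0.05.

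Across genes, the differences of KO and of HET from WT had a correlation of 0.37 and a covariance of 0.0106, and 63.5 percent of genes had the same sign. Genes are not independent replicates, and both differences share the WT arrays. Simulated unchanged arrays with independent genes, where both groups shared the simulated WT arrays, gave a mean correlation of 0.41, a covariance of 0.0126 and the same sign in 63.3 percent. With residuals shuffled by whole arrays, which keeps the correlation between genes, the mean was 0.39. The central range of these 100 simulations was -0.22 to 0.78, so the observed correlation is not set apart from unchanged groups. With the WT arrays split between the comparisons, the correlation had a median of 0.03 over 20 splits, between -0.19 and 0.12. Against all WT arrays it was 0.168 without HET 6. For genes near Rb1 no excess of small p-values was found. Of 167 genes within 20 Mb, 2.99 percent had an unadjusted p under 0.05 in KO against WT, and of 10887 other genes 2.55 percent did (Fisher's exact test, two-sided, p = 0.62). A test of called genes was void with 0 calls.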

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

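The tests of gene counts over other splits, the permutation and dividing-cell tests of the E2F targets, the comparison of meiotic with spermatogonia genes, and all tests of switching genes and of Esd were chosen only after the result was seen. The tests of list counts over other splits were not. The gene length tests were chosen after the meiotic shifts and each array's correlation with gene length had been seen, but before their own result. The test of the E2F targets with the meiotic covariate was also added after seeing the data, but before its own result.

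Other splits of the same arrays into groups of the same sizes were fitted in the same way, without regard to whether Eif2s3y was detected on an array. In KO against WT, 6 lists passed with the real groups, 29 of 100 splits gave as many, and the highest of the others was 13, so chance is not excluded. In KO against HET, 2 lists passed, 21 of 35 splits gave as many, and the highest of the others was 6, so chance is not excluded there either. In HET against WT, 0 lists passed, so all 56 of 56 splits gave as many, and the highest of the others was 12. A real count of 0 fixes the share in the same way for genes, with 100 of 100 splits in KO against WT (highest of the others 2), 56 of 56 in HET against WT (302), 35 of 35 in KO against HET (1) and 100 of 100 in the F-test (5). The 302 genes came from WT 8, WT 12 and HET 7 set against the other WT and HET arrays, which points to a structure of the samples that genotype does not give.

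E2F targets were higher in KO than in WT by 0.096 on the log2 scale. A difference in the level of meiotic genes, taken as a linear effect over all arrays, did not account for the shift. The shift with the meiotic list mean as a covariate was 0.10, or 1.04 of its value, with a camera adjusted p of 1e-06 at the preset correlation. Without the covariate the adjusted p was 0.22 with an estimated correlation. The covariate was set mostly by WT 12, HET 7 and HET 6, whose E2F target means were 0.015, -0.006 and -0.032. It therefore cannot decide on smaller differences among the other arrays. Among WT 8 to WT 11, WT 8 was highest (0.105 in both the meiotic and the E2F target list) and WT 11 lowest in both (-0.299 and -0.066). KO 2 and KO 3 went the other way, with meiotic means of -0.227 and -0.196 and E2F target means of 0.147 and 0.144. The covariate holds meiotic prophase genes only, so it cannot decide on germ cells of other stages. Variation between animals or arrays that these genes share, unrelated to genotype, may be the source, as the exact two-sided permutation p of the list mean was 0.079, and 0.083 within the low- and the high-number set of arrays. A larger share of dividing cells cannot be told apart from a change in E2F targets alone, since the G2/M list differed by 0.031 (exact two-sided permutation p = 0.6, adjusted p = 0.79 with an estimated correlation), passed with the preset correlation only without WT 8, with array weights or with the stricter filter, and the exact two-sided permutation p for the difference between both lists was 0.095. Loss of Rb1 stays open as a biological explanation, as genotype is the difference the design names.

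Meiotic genes stood apart in WT 12 (0.68), HET 7 (0.75) and HET 6 (-0.89), arrays of different genotypes. More or fewer germ cells of all stages is argued against, since the spermatogonia list did not follow the meiotic list in any of the 3 arrays (-0.08, -0.13 and 0.02, highest ratio to the meiotic shift -0.03). In HET 6 it was near the WT mean, as in WT 8 (0.028), and not shifted the other way. The pan-germ cell list, though, moved the same way as the meiotic list by less (0.25, 0.27 and -0.13). A bias tied to gene length is argued against as the source of the meiotic shift, with the shift at percentile 100 in WT 12 and HET 7, and 0 in HET 6, among 10000 lists matched on length and level. HET 6 did carry such a trend over all genes, with a rank correlation across genes of 0.33 between its deviation and gene length against -0.10 to 0.07 in the other arrays, so a difference in RNA quality in HET 6 stays open beside the meiotic shift, which lay outside the matched range of -0.23 to 0.16. A difference in how far the first meiotic wave had come in these testes is a hypothesis that was not tested, since litter and exact age are not given in the sources used here.

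Across arrays, 58 genes switched between a low and a high level with a gap of at least 1, among them Uap1, Fcer1g and F11r, all high in WT 10, HET 6, HET 7, KO 1 and KO 2 (low readings of Fcer1g, on 7 arrays, were not above background). Of these genes, 0 parted all KO from all WT arrays, and the most that any of 126 splits of these arrays parted was 2. This is no separate test of genotype, as 0 genes had passed in limma and the 23 genes high in WT 12 and HET 7 alone could not part KO from WT. Variants of mixed parental strains inherited in blocks are a candidate explanation, since 58.3 percent of pairs within 10 Mb parted the arrays alike, with at most 1 array differing, against 17.1 percent of pairs on different chromosomes (permutation p = 5e-04, the smallest that 2000 permutations give), and 76.9 against 0.2 percent without the 23 genes high in WT 12 and HET 7 alone. Near Rb1, Esd was detected only in 5 arrays (5.18 to 6.42, against 4.59 to 4.72 in KO 1 to 4 and WT 8 to 10), and 2 of 81 other genes within 10 Mb (Entpd4 and Piwil2) parted these arrays against 22 of 10973 elsewhere (Fisher's exact test, two-sided, p = 0.013). This grouping replaced a first one, by the largest gap in Esd, which set WT 12 alone apart and gave no excess (23 of 81 against 2285 of 10973, Fisher's exact test, two-sided, p = 0.1), so a strain variant beside the floxed allele may be involved but rests on the grouping chosen. Fisher's test also counts genes as independent. Entpd4 and Piwil2 lie in the same region and may be inherited together, so its p-value cannot measure chance for such a block.

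Of 402 groups of 4 or 5 values, 29 held an array whose gap to the nearest other array, as a share of the group's range, passed Dixon's critical value, where about 20 are expected by chance. HET, with 3 arrays, was not tested. In KO 1 these were the mean of the cholesterol list (0.942, low), Ccdc136 (0.833, high), Cxadr (0.934, low), E2f1 (0.884, low), Insig1 (0.883, low) and Zfp760 (0.855, high). In KO 2 they were Actg2 (0.861, high) and Tex11 (0.929, high). In KO 3 they were Col1a2 (0.885, low), Cyb5a (0.952, high), Hspa1a (0.832, low), Tagln (0.886, low), Tfdp2 (0.904, high) and Tyrobp (0.973, low). In KO 4 they were Alas2 (0.868, low), E2f6 (0.94, low), Hba-a1 (0.891, low), Igfbp3 (0.872, high) and Laptm5 (0.899, high). In WT 12 they were the mean of the spermatogonia list (0.769, low), Dnajb1 (0.783, high), Hspb1 (0.771, low), Mnd1 (0.823, high) and Zbtb16 (0.771, low). In WT 8 they were Cdkn1b (0.804, high), Mrc1 (0.766, low) and Plk1 (0.753, high). Col1a1 in WT 9 (0.726, high) and Adipoq in WT 10 (0.758, high) complete the list.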

How the results depend on the processing

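Leaving out WT 12, HET 6 and HET 7 together, the meiotic covariate, single probes, the number sets as a block, lists without Fcer1g and F11r and the exact permutation test were chosen after the data were seen. The leave-out of the 3 arrays leaves 1 HET array, whose spread is assumed to be like that of the other groups. Counts of lists for its HET contrasts are therefore not given. In limma, the count of genes past the threshold was 0 in KO against WT in all other settings and in each fit without 1 array. Without those 3 arrays it was 2 (Prcp and Sncb, 676 genes at an unadjusted p under 0.05), and the F-test gave 1 (Prcp, chosen after its values were seen). Without 1 array the counts of genes ranged from 0 to 173 in HET against WT, 0 to 62 in KO against HET and 0 to 9 in the F-test, each highest without HET 5. Counts of lists without 1 array ranged from 4 to 8 in KO against WT (without WT 9 and WT 8), from 0 to 5 in HET against WT and from 0 to 5 in KO against HET. In KO against WT, 2 lists passed with WT and HET together as the control, 0 with the estimated correlation and 0 by permutation. In HET against WT, 1 passed with the stricter filter and 4 with array weights. In KO against HET, 5 passed with array weights and 0 with the estimated correlation, while the permutation test could give 0 only, as its smallest p is 0.057. The E2F target list passed in KO against WT in 27 of 28 alternatives, all at the preset correlation, with medians from 0.0739 to 0.1224. These alternatives are not separate checks. The authors' values repeat the quantile normalization without background correction. Leaving out a HET array alters the estimated spread but no KO against WT difference, and Fcer1g and F11r are not members of the list. The call was lost with the estimated correlation (adjusted p = 0.22), the only one of these 28 that drops the preset. In the exact permutation test, which does not use the preset either, its adjusted p was 0.44. In KO against HET it passed in 22 of 27. The median of the meiotic prophase list in HET against WT was 0.1717 with array weights, 0.2558 without HET 6 and -0.3995 without HET 7. In KO against HET it was -0.3555 without HET 6 and 0.3386 without HET 7. Without the 3 arrays the epididymis, fat and striated muscle list had a median of 0.1419 in HET against WT, and the endothelial list -0.1193 in KO against HET. The difference of the brighter Rb1 probe ranged from -0.4062 to -0.1892 in KO against WT, from -0.107 to 0.0936 in HET against WT and from -0.3719 to -0.1511 in KO against HET without 1 array, and without the 3 arrays it was -0.2779, -0.3101 and 0.0322 in turn. With the mean of both probes the HET against WT difference was -0.2236 and that of KO against HET -0.139. The correlation of the KO and HET differences from WT ranged from 0.1683 (without HET 6) to 0.4557 (without WT 8). The dimmer probe's KO against HET difference ranged from -0.192 to 0.0204 without 1 array and was 0.0174 without the 3 arrays. The cause of these changes was not tested, except that HET 6 and HET 7 hold opposite meiotic levels and the leave-outs use fewer arrays. Of the other list values in KO against WT, 523 of 616 kept the direction of the camera test and the side of the threshold, 27 lost the call, 15 gained one, and 51 changed the direction of the test with no call. The slide block was not run because slides are not given in the sources used here. No paired analysis was possible because the groups share no replicate numbers. With both number sets as a block, 6, 0 and 3 lists passed in KO against WT, HET against WT and KO against HET, and 0 genes in each. Between 39.3 and 43.7 percent of probes per array were above background, which limits what can be said of dim genes.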

Other observations

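Leydig cell genes varied between arrays within each group, in genes chosen after their values were seen. Cyp17a1, an enzyme of androgen synthesis, read 9.73 in WT 11, 9.46 in HET 5, 9.92 in KO 1 and 10.24 in KO 3, and 11.29 to 12.64 in the other arrays. In the same 4 arrays the mean of the Leydig list, which passed, lower in KO, with the preset correlation but had adjusted p = 0.19 with an estimated one, was -0.152, -0.36, -0.258 and -0.299, against -0.154 to 0.132 in the others. In them Star read 4.59, 4.57, 4.66 and 4.72, not above background, and neither was the 5.05 of KO 2. In the other 7 arrays, on which it was detected, Star read 5.48 to 6.52. Mrap, an accessory protein of the melanocortin receptor, read 5.61, 5.75, 6.02 and 5.61, against 6.06 to 7.95. Cyp11a1, which opens steroid synthesis from cholesterol, read 7.52, 7.07, 7.12 and 7.19, against 7.42 to 8.19.

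Hspa2, a chaperone of spermatocytes also chosen after its values were seen, read 12.77 in WT 12 and 12.98 in HET 7, 11.55 in HET 6 and 11.58 to 12.02 in the other arrays. The mean of the immature Sertoli cell list, relative to the WT mean, was -0.265 in WT 12 and -0.516 in HET 7, and between -0.204 and 0.224 in the other arrays. The probe for the Y-linked gene Eif2s3y was detected only in WT 8, WT 9, HET 5, HET 6, KO 1 and KO 2, with a gap of 2.34 to the other arrays. These are also the 6 arrays with the lowest numbers in the column names. Between these and the other arrays, with genotype in the limma fit, 1 gene passed (Eif2s3y itself), and 792 had an unadjusted p under 0.05 where 554 are expected by chance. As all samples are testes, its readings in the other 6 arrays cannot be taken as the level of the gene.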
